A study of Homo sapiens with 8 samples.

How the data were processed

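Cells positive for CD34 and negative for CD105 were obtained by collagenase digestion of renal artery and fluorescence-activated sorting, per the labels' protocols. RNA was isolated with a mirVana kit and cDNA was run on a real-time PCR instrument with FAM-labelled TaqMan assays, per the labels' protocols. The type of card, the reverse transcription, any preamplification, the Ct thresholds and the identity of the reference were not given in the sources used here. Groups were taken from the sample titles (4 samples after short and 4 after long warm ischemia).

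The authors deposited a table of Ct values without normalization, a table of normalized values and a table of fold changes. The Ct table held 760 rows for 754 unique assays. For the 6 repeated assays at most 1 copy held values. Of 493 determined Ct values, 99 were over 35. The normalized table held 489 delta Ct values, which the authors made by subtracting a reference value from each Ct, so that minus delta Ct is a log2 relative quantity. The subtracted value was inferred as Ct minus delta Ct and was near constant within a sample. Of 482 values that could be compared, 14 in the short and 4 in the long group lay over 0.5 cycles from their sample's median subtracted value, the largest by 4.07 cycles. The deposited fold changes are a linear ratio of long over short. They were recomputed from the group means of delta Ct, and 79 of 79 agreed within 1%. In 10 assays the tables disagreed on which samples had a value, with 7 delta Ct values without a Ct and 11 Ct values without a delta Ct. No rows for U6 or other small RNA reference assays were found in the tables, and the 2 plant control assays had 0 Ct values.

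An assay was taken as detected at a Ct of at most 35 and was tested when detected in at least 3 of 4 samples of each group, which left 31 assays. Undetected values were missing in the fit. Minus delta Ct was fitted by group with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 31 assays and a threshold of 0.05. The moderation by limma was complete, so that all assays shared 1 residual SD, which was 3.24 on the log2 scale. Named assays were also compared by exact permutation of the group means (70 arrangements of 4 against 4, smallest two-sided p 0.0286). Detection was compared per assay with Fisher's exact test. Lists of microRNAs (27) for hypoxia, kidney injury, vessel and blood cell types, kidney epithelium, stroma, renal cancer, apoptosis, inflammation and genomic clusters and families were tested with camera (preset correlation 0.01) where at least 3 members were tested. Detections per sample in each list were compared by exact permutation. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

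The named assays followed a rule. The 12 largest changes per direction past the threshold were taken, with free places filled by the smallest unadjusted p in that direction. Added to these were list members that passed (2 to 4 per list), miR-210, miR-21, miR-126, reference small RNAs, the 3 largest changes per direction in the authors' table, and up to 10 assays per direction detected in every sample of 1 group and none of the other. Only 1 assay lay above 0, so the rising places could not be filled. miR-223 is named as a member of the platelet list, but it was not among the named assays of the exact test's adjustment and the alternatives. Its values in the last part were picked after they were seen. Any other assay named outside this rule was chosen after its values were seen.

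The alternatives were other normalizations (mean Ct of the 18 assays detected in all samples, quantile, sample median, none), detection limits of 32 and 40, undetermined values set to 40, filters of all 8 or at least 2 of 4 samples per group, trend and robust options, an unmoderated two-sample test, sample weights, the patient number as a block and each sample left out. The test was tried on simulated panels of 31 assays (100 panels for each kind of noise). The independent noise had the spread of the mean Ct normalized values, not that of the minus delta Ct used in the main test. With this noise the test recovered 64.3% of changes of 4 cycles and 95.5% of changes of 8 cycles, with 4.34% false calls. With shifts shared by all assays of a sample it recovered 18.8% and 68%, with 16.2% false calls. In the real values the mean correlation of residuals between assays was 0.787 in minus delta Ct and -0.04 after mean Ct normalization. No coordinates are given, since the tables name no genome build. Assay names were used as deposited and were not checked by other means. The RefSeq gene table of GRCh38.p14 was used only to find which microRNA genes lie within 10 kb of each other.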

Results

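MicroRNA levels were measured by TaqMan real-time PCR in cells that carried CD34, a surface marker of vascular and blood-forming progenitors, and lacked CD105 (endoglin). The cells had been sorted from digested human renal artery. The short warm ischemia group held 4 samples with 5 min of warm ischemia from living donor kidneys, and the long group held 4 samples with 30 min from kidneys removed for renal cell cancer. Each sample came from a different patient, so the length of ischemia cannot be told apart from the disease and the operation. Of 754 unique assays, 105 gave a threshold cycle (Ct) of at most 35 in any sample and 18 did so in all 8 samples. The number of assays detected in a sample was 54, 45, 50 and 42 in the short group and 40, 55, 52 and 56 in the long group. The group means were 47.8 ± 5.32 and 50.8 ± 7.37 assays (SD, n = 4 each; exact permutation p = 0.571, two-sided). None of the 17 let-7 assays, a family abundant in most tissues, was detected in any sample, while 7 Ct values of miR-1243 were under 10 cycles. In 10 assays, miR-218 among them, the Ct and normalized tables disagreed on which samples had a value. Assay names are those of the tables, and whether any name or entry was misassigned was not settled here, which limits what each named value means. No depth of reads exists for this assay, and the small number of samples limits the precision of every value.

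The comparison asked which microRNAs differed in these cells between long and short warm ischemia. In the authors' normalized values, miR-618 and miR-29c, a microRNA known to repress collagen and other matrix genes, fell in the long group. The relative level of miR-618 was 8.27 ± 2.72 (log2 scale, SD, n = 4) after short and -0.03 ± 5.59 (n = 3) after long ischemia, a log2 change of -8.30 ± 2.47 (SE) with a limma adjusted p of 0.0184. For miR-29c the levels were 7.54 ± 3.32 and -0.02 ± 8.998 (n = 4 each), a change of -7.56 ± 2.29 (limma adjusted p = 0.0184). These SEs come from the residual SD that all assays shared, not from the spread of each assay. With the unmoderated test the adjusted p was 0.258 for miR-618 and 0.269 for miR-29c. Without long sample 2 alone, the changes were -5.27 for miR-618 and -3.40 for miR-29c (limma adjusted p = 0.215 and 0.36, the highest with any 1 sample left out). The lowest limma adjusted p values were 0.00568 and 0.000589, both without long sample 3. For miR-618 that sample had a Ct over 35 and was already missing from the fit. With any Ct under 40, miR-618 had a value in all 4 long samples and a change of -10.86 (limma adjusted p = 0.000384). At a Ct of at most 35, the levels of miR-618 and miR-29c overlapped between the groups. Their exact permutation p values were 0.0571 and 0.143. No assay rose past the threshold, and the 9 assays with an unadjusted limma p under 0.05 were all lower in the long group.

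Nearly all tested assays lay lower in the long group on this scale. The median change over the 31 tested assays was -3.46, and 30 of them were below 0. Relative to that median, miR-618 stood at -4.85, miR-29c at -4.10 and miR-150 at 7.46. The reference value that the authors subtracted was 27.04 ± 1.52 cycles in the short and 23.7 ± 3.26 cycles in the long group (SD, n = 4 each), a difference of -3.34 cycles (exact permutation p = 0.114). The mean Ct of the 18 assays detected in all samples was 24.6 ± 0.446 and 25.2 ± 0.863 cycles (exact permutation p = 0.343). With each sample normalized to that mean Ct, the median change was -0.23 and 18 of the 31 assays were below 0. The assays below 0 numbered 14 with quantile normalization, 21 after subtracting each sample's median and 19 without normalization. The 18 common assays are among the 31 tested and include miR-29c and miR-1243. The mean Ct scaling therefore centres the changes near 0 by construction. Quantile and sample median scaling do the same. Only the count without normalization was free to show a general fall. Under each of these 4 scalings limma called 0 assays at an adjusted p of 0.05, with 4, 2, 3 and 2 assays at an unadjusted p under 0.05.

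**Figure D1:**
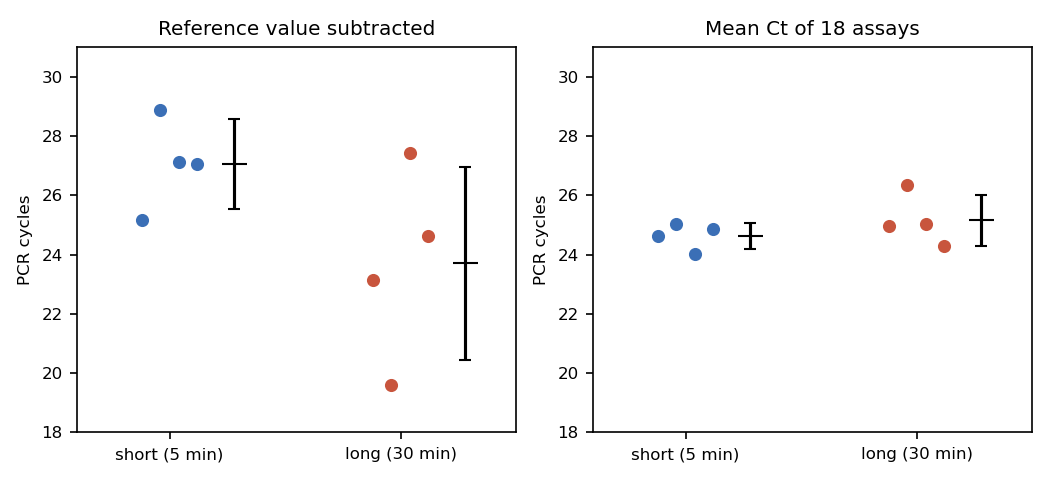
Reference value subtracted by the authors (left) and mean Ct of the 18 assays detected in every sample (right), in PCR cycles, for the 4 samples of each group, with the mean and SD as a black bar. The reference spans 19.6 to 28.9 cycles over the 8 samples, while the mean Ct spans 24.01 to 26.4 cycles.

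With mean Ct normalization the change of miR-618 was -3.01 ± 1.35 (limma adjusted p = 0.381) and that of miR-29c was -3.54 ± 2.27 (limma adjusted p = 0.568). With 1 sample left out these ran from -4.00 to -1.98 for miR-618 and from -4.96 to -1.15 for miR-29c, the lowest without short sample 4 and the highest without long sample 2. The number of assays called in the authors' values also rested on single samples. Without short sample 1, 2 or 3, or without long sample 1, limma called 0 assays (10, 5, 2 and 4 at an unadjusted p under 0.05). Without long sample 2 it called 1 assay, miR-367, and without long sample 3 it called 11. Without short sample 4 it called 3.

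The assays nearest to the threshold below miR-618 and miR-29c did not pass. Among them miR-363, of the miR-106a cluster, had a log2 change of -6.51 and miR-367, of the pluripotency-associated miR-302 cluster, one of -6.43 (limma adjusted p = 0.0787 for each). With 1 sample left out, the change of miR-367 ran from -9.11, without short sample 4 (limma adjusted p = 0.00988, the lowest), to -3.40, without long sample 1 (limma adjusted p = 0.427, the highest). For miR-302c of the same cluster the change was -4.96, and for miR-218, a microRNA encoded in SLIT genes, it was -5.55 (limma adjusted p = 0.157 for each). For miR-218, which had a normalized value in 4 short and 3 long samples, the groups did not overlap (exact permutation p = 0.0286, the smallest that these samples can give, and 0.182 after adjustment). Of the remaining named assays, miR-381 stood at -4.86, miR-1243 at -4.72, miR-523 at -4.53, miR-338-5P at -4.24, miR-720 at -4.22 and miR-1274B at -4.21. Without long sample 2 these values and those of miR-218 and miR-302c were smaller: -2.99 for miR-381, -1.88 for miR-1243, -2.83 for miR-523, -1.76 for miR-338-5P, -2.94 for miR-720, -2.41 for miR-1274B, -3.31 for miR-218 and -3.09 for miR-302c. Quantile normalization turned the direction of miR-218 (1.13), miR-381 (0.17) and miR-338-5P (0.14). The mean Ct normalization brought the changes of miR-218, miR-302c, miR-381 and miR-1243 to -0.95, -0.98, -0.84 and -0.85. It brought those of miR-523, miR-338-5P, miR-720 and miR-1274B to -0.52, -0.37, -0.34 and -0.34. On that scale the change of miR-338-5P turned to 0.50 without short sample 2. The change of miR-720 turned to 0.34 without long sample 3 and that of miR-1274B to 0.25 without long sample 1. The change of miR-523 kept its sign (-0.03 without short sample 3). Without long sample 2 that of miR-1243 turned to 0.23, and without short sample 3 those of miR-218, miR-302c and miR-381 were -0.37, -0.55 and -0.54. The lowest values with 1 sample left out were -1.57 for miR-218 (short sample 2), -1.75 for miR-302c and -1.44 for miR-381 (short sample 4), and -1.42 for miR-1243 (long sample 3). Under it miR-363 stood at -2.37 ± 1.04 with no overlap between 3 short and 4 long samples (exact permutation p = 0.0571, limma adjusted p = 0.381), and miR-367 at -4.19 ± 2.64 (limma adjusted p = 0.568). With 1 sample left out, the mean Ct change of miR-367 ran from -6.73, without short sample 4, to -2.20, without long sample 1, and its limma adjusted p from 0.0479, without short sample 4, to 0.946, without short sample 1.

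**Figure D2:**
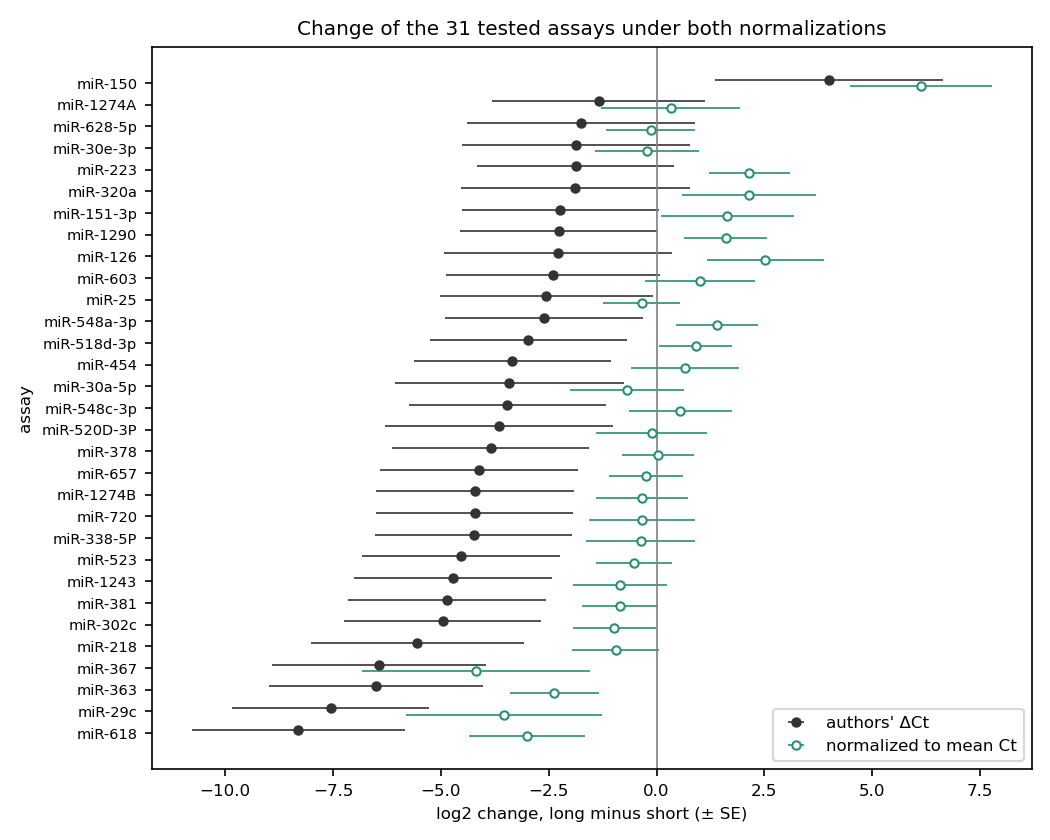
Log2 change of each of the 31 tested assays, long minus short, with its SE, in the authors' values (filled) and normalized to the mean Ct (open). In the authors' values 30 assays lie below 0, against 18 with the mean Ct normalization, which centres the tested assays by construction.

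The assay with the highest change was miR-150, a microRNA abundant in mature lymphocytes. Its level was -4.16 ± 2.43 after short and -0.16 ± 1.28 after long ischemia (SD, n = 3 each), a change of 4.00 ± 2.64 that did not pass (limma adjusted p = 0.258). It was the only tested assay above 0 in the authors' values, and its groups did not overlap (exact permutation p = 0.1, the smallest that 3 samples against 3 can give). This rested on long sample 2, with a Ct of 23.6 and a level of -0.50. The median value subtracted in that sample was 19.6 cycles. With that value the level would be lower and inside the short range of -5.81 to -1.38. The sample without a value in each group was left out of these means, and with undetermined values set to a Ct of 40 the change was 1.57 (limma adjusted p = 0.766, the highest of the alternatives, against a lowest of 0.129). With mean Ct normalization the change was 6.13 ± 1.65, with an unadjusted p of 0.00458 and a limma adjusted p of 0.142. Leaving out 1 sample at a time, that adjusted p ran from 0.0446, without short sample 4, to 0.647, without short sample 3. The endothelial miR-126 had a change of -2.29 ± 2.64 (limma adjusted p = 0.462), which turned to 2.52 ± 1.36 with the mean Ct (limma adjusted p = 0.568), 1.81 with quantile normalization, 1.67 with the sample median and 1.81 without normalization. Without long sample 2 the change of miR-126 was -1.48 in the authors' values and 1.33 with the mean Ct, and without short sample 3 the latter was 1.66.

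Of the 27 lists fixed in advance, 5 held at least 3 tested members. The platelet list, with miR-126, miR-150 and the myeloid miR-223, was higher in the long group relative to the other assays (camera adjusted p = 0.0148 over the 5 lists, and adjusted p = 0.0974 with an estimated correlation). Its median change was -1.88 against -3.75 for the other assays, so the median and the test differed in sign, and 1 of its 3 members lay above 0. With mean Ct normalization its median was 2.52 (camera adjusted p = 0.00137 with the preset correlation). An estimated correlation was not tried on that scale, so this p may be too small. Without long sample 4, camera called 0 lists. The leukocyte list (miR-150, miR-223 and miR-363; adjusted p = 0.236), the endothelial list (miR-126, miR-151-3p and miR-218; adjusted p = 0.906), the list of microRNAs lower in clear cell renal cancer (miR-218, miR-30a-5p and miR-363; adjusted p = 0.467) and the placental C19MC cluster (miR-518d-3p, miR-520D-3P and miR-523; adjusted p = 0.906) did not pass camera. Adjusted over the list alone, limma called 2 members of the renal cancer list and 1 of the leukocyte list, against 0 over all assays tested. It called 0 members of the platelet, endothelial and C19MC lists either way. The platelet list shares miR-150 and miR-223 with the leukocyte list and miR-126 with the endothelial list.

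**Figure D3:**
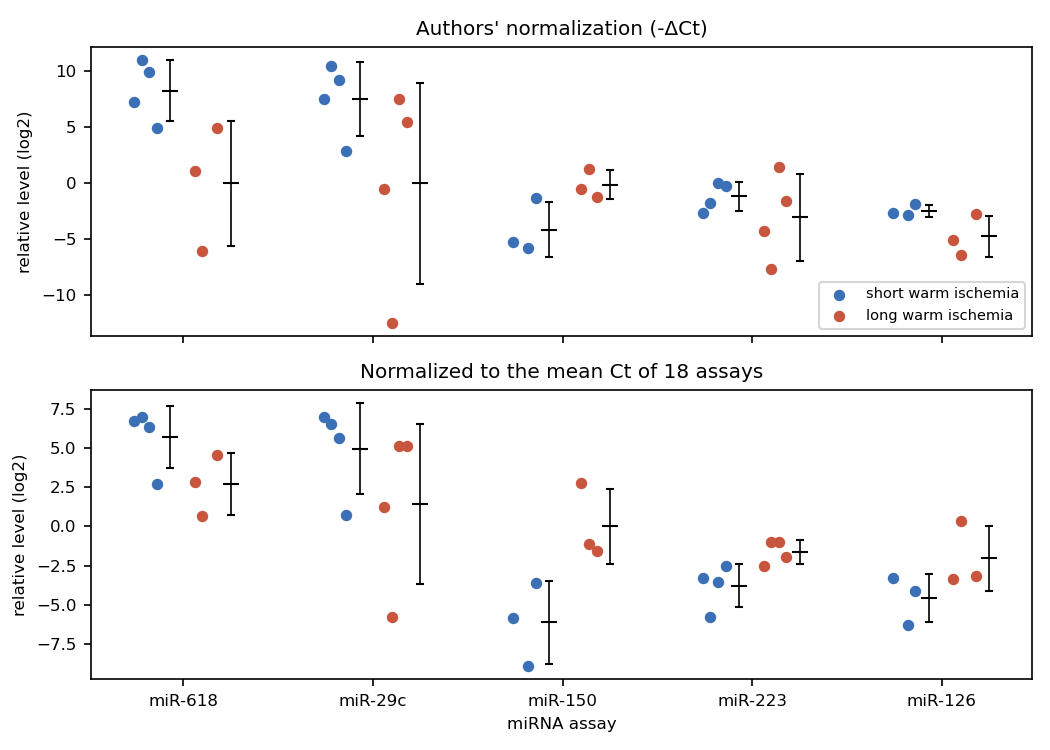
Relative level (log2) of miR-618, miR-29c, miR-150, miR-223 and miR-126 in each sample where it was detected, with the mean and SD, in the authors' values (top) and normalized to the mean Ct (bottom). The changes of miR-126 and miR-223 are -2.29 and -1.88 in the authors' values and 2.52 and 2.15 with the mean Ct, and miR-150 is higher in the long group in both panels.

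Whether an assay was detected at all was compared apart from its level. miR-16, a repressor of BCL2, and miR-222, a repressor of KIT, were each detected in 4 of 4 long and 0 of 4 short samples. Their mean Ct in the long group was 28.4 ± 1.94 for miR-16 and 30.4 ± 2.26 for miR-222 (SD, n = 4). Fisher's exact test gave p = 0.0286 for each, the smallest that 4 samples against 4 allow, and 0 of the 87 assays tested passed after adjustment. These 2 were the only assays with an unadjusted p under 0.05. No assay was detected in every short and no long sample at a Ct of at most 35. The hypoxia-induced miR-210 was detected in 0 of 8 samples, and miR-21, a microRNA raised in many injured tissues, in 1 of 8.

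By list, detection did not differ between the groups after adjustment. The miR-15, miR-16 and miR-195 family was detected 6 times in the long and 0 times in the short samples, and the miR-221 and miR-222 cluster 4 and 0 times (exact permutation p = 0.0286 for each, adjusted p = 0.371). Hypoxia-induced microRNAs were detected 4 times in the long and 4 times in the short samples, those of kidney ischemia and reperfusion 10 and 7 times, and angiogenesis regulators 19 and 10 times. The counts were 16 and 15 for endothelial, 2 and 3 for smooth muscle, 10 and 12 for kidney epithelial and 7 and 5 for stromal microRNAs. Among blood-related lists they were 17 and 13 for leukocytes, 16 and 10 for blood progenitors, 13 and 7 for red cells and 19 and 14 for platelets. MicroRNAs raised in clear cell renal cancer gave 12 and 5 detections and those lowered in it 13 and 15. For the p53 and apoptosis list the counts were 6 and 3, and for the inflammation list 9 and 5. The miR-17 cluster gave 7 and 6, the miR-106b cluster 5 and 7, the miR-106a cluster 6 and 5, the miR-23 cluster 1 and 2, the DLK1-DIO3 cluster 10 and 9 and C19MC 14 and 17. The miR-29 family gave 5 and 4, the miR-30 family 8 and 7 and the miR-200 family 0 and 1. Leaving aside the let-7 family, which had 0 detections, the adjusted p of every list was 0.371 or higher.

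The authors' deposited table of fold changes gave 79 linear values, long over short, of which 69 were below 1 and 10 above, with a median of 0.131. In the authors' deposited table the highest were miR-30c at 1245, miR-30b at 28.9 and miR-150 at 16.04, and the lowest were miR-141# at 3.42e-07, miR-409-3p at 4.54e-05 and miR-518b at 0.000138. The values for miR-30c, miR-30b and miR-141# in the authors' deposited table each rested on 1 sample per group, and 31 of the 79 had 1 sample in at least 1 group. For all 31 assays tested here, the direction in the authors' deposited table was that of the limma change in their normalized values. This was close to fixed in advance, since both are differences of group means of the same delta Ct values. With mean Ct normalization the direction was shared by 19 of the 31.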

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

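All tests of explanations in this part were chosen only after the result was seen. Both bounds for the low Ct assays, and the measures for the reference, for the single sample and for more template, were revised after their first values were seen. Under the first versions, signal not specific to the named miRNA had come out as favoured, cluster transcription and the single sample as argued against, and more template as open. The first reference measure was set aside because it centred the tested assays by construction, and the first measure for the single sample because it came out alike whichever sample was left out.

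In the short group, the lowest sample for miR-367 stood at -4.80 on the log2 scale, far from the other samples at 5.53 to 6.09. It was the 1 such sample found in 28 checks, and chance gives about 1 in 20.

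For miR-26a, 2 long samples had a delta Ct and no Ct value, so these values entered no comparison.

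The general fall in the authors' normalized values is the first pattern. Less template in the long group is argued against, since the median change without normalization was -0.50. The direction of the fall was kept without the 1 long sample with the lowest reference value (long sample 2), with 30 of the 31 assays still below 0. That count was the same whichever sample was left out, and the residuals of the assays were correlated (mean 0.787). The count therefore cannot weigh the part of any 1 sample. The share of long sample 2 in the size of the fall cannot be told apart. Without it the median moved from -3.46 to -2.36, neither near 0 nor unmoved. The lower subtracted reference value in the long group enters the fall by arithmetic. Where the same samples enter, each change is the change without normalization plus the difference of the values subtracted in them. That difference varied between assays, since missing samples and single subtracted values differed. The change went from -3.58 to -8.30 for miR-618 and from -1.38 to -4.72 for miR-1243. The sample medians of the reference differed by -3.34 cycles. The median change was -0.50 without and -3.46 with the subtraction, so most of the latter comes with it. Why the reference differed between the groups is open. Whether the reference itself responded to ischemia, cancer or the amount of RNA was not tested.

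Of the 35 splits of the 8 samples, 5 gave a median change as large as the real one, the highest other split reaching 4.34 in size. For the number of assays called, 3 splits gave at least the real 2 calls and the highest other split gave 5. Chance is excluded for neither.

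The second pattern is a group of 6 tested assays with a mean Ct under 22. Transcription of the genomic cluster around the assay and signal not specific to the named miRNA cannot be told apart here. Of the measurements of neighbouring guide strand assays, 8.33% were detected (16 of 192), against 12.5% for the other tested assays with neighbours (39 of 312). Of the 192, 120 belonged to miR-381 with 0 detected, while the share was 25% for miR-302c and 33.3% for miR-657, 0 of 8 measurements were detected for each of miR-29c and miR-1243, and miR-618 had no neighbouring assay. Names were matched to genes with hyphens removed, so miR-1243 may also have matched a numbered copy of another microRNA gene. Its 8 measurements, counted in the 192, may therefore not be those of a true neighbour. Signal not specific to the named miRNA may account for part of the pattern, since 7 Ct values, all of miR-1243, were under 10 cycles.

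The third pattern joins miR-150, miR-126 and miR-223, high against other assays, with miR-16 and miR-222, detected in the long group. Blood cells carried over in the long samples are a candidate source: of 30 other assays on the leukocyte, red cell and platelet lists, 3.5 ± 0.577 were detected per short and 5.75 ± 0.957 per long sample (SD, n = 4 each; exact permutation p = 0.0286, unadjusted). Of the 30, 13 were detected at all, 9 in more long and 3 in more short samples. The members of the 30 with a tested level, miR-363 (counted among the 9) and miR-25, lay lower in the long group. Their changes were -6.51 and -2.56 in the authors' values and -2.37 and -0.34 with the mean Ct, which does not go with this source. miR-142-3p, abundant in leukocytes, was detected in 1 of 4 long and 0 of 4 short samples, and miR-451, abundant in red cells, in 2 of 4 long and 0 of 4 short samples, while miR-486-5p and miR-144, also of red cells, were detected in 0 of 8, the sort on CD34 would remove most mature blood cells, and 15 of the 30 assays are also on another list. More template in the long samples by over 1 cycle is argued against. The mean Ct of the 18 common assays, miR-29c and miR-1243 among them, was 0.531 ± 0.486 cycles (SE) higher there. The median Ct of all detected assays went the other way, at 28.5 ± 0.74 in the long and 29.1 ± 0.937 in the short group (SD, n = 4 each). The number of assays detected per sample, 50.8 against 47.8, did so too. A smaller difference of template stays open. A response of the cells to ischemia or to the disease was not tested and stays open.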

How the results depend on the processing

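All but 5 of the alternatives in this part were chosen before the data were examined. The 2 calls became 0 with mean Ct, quantile or sample median normalization, without normalization, with undetermined values set to a Ct of 40, with trend and robust options and with the unmoderated two-sample test. They became 1 with a Ct of at most 32 (miR-618) and with detection in all 8 samples (miR-29c). Sample weights gave 3 (miR-363, miR-367 and miR-618), detection in at least 2 of 4 samples gave 2 (miR-618 and miR-875-5p), both without miR-29c, and any Ct under 40 gave 2 (miR-618 and miR-29c). Leaving out 1 sample gave 0 to 11 calls, with 0 without short sample 1, 2 or 3 or long sample 1, 1 without long sample 2, 2 without long sample 4, 3 without short sample 4 and 11 without long sample 3. Of the alternatives chosen after seeing the data, each sample's median subtracted value and leaving out Ct values under 15 gave 2 calls each. Of 31 assays tested, 24 were left with a Ct of at most 32 and 18 with detection in all 8 samples, against 35 with any Ct under 40 and 38 with detection in at least 2 of 4. The cause of the other shifts was not tested.

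With the patient number as a replicate block, limma called 0 assays (3 at an unadjusted p under 0.05), and the replicate block on values normalized to the mean Ct, chosen after seeing the data, also gave 0. The samples share only a number: the correlations of deviations between samples of the same number were -0.58, -0.24, 0.26 and -0.32, and 1 of the 4 numbers correlated best with itself. The replicate block left 1 list past the threshold.

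The 1 list past the threshold became 0 with an estimated correlation and ranged from 0 to 1 when 1 sample was left out (0 without long sample 4). It stayed 1 with the mean Ct normalization, chosen after seeing the data and run with the preset correlation only. Assays detected in all 4 samples of 1 group and none of the other numbered 2, against 1 at a Ct of at most 32 and 3 at any Ct under 40. Directions shared with the authors' folds numbered 31, against 1 when the folds were read as log2 values and 19 after mean Ct normalization, chosen after seeing the data. The count of 1 was fixed in advance, since linear folds are all positive and only miR-150 lay above 0. 

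The log2 change reversed with quantile normalization for miR-218 (1.13), miR-381 (0.17), miR-338-5P (0.14) and miR-126 (1.81). For miR-126 it also reversed with the mean Ct (2.52), the sample median (1.67), no normalization (1.81) and the replicate block on mean Ct values (0.47). The cause was not tested. Of the other values of named assays under an alternative, 275 did not turn and kept their side of the threshold (miR-1243 was at 0 with quantile normalization), 31 were no longer past it and 12 were newly past it. U6, the reference small RNA assays (for assays and lists) and fry were not run: the tables used here hold no such reference rows, and no list had 3 members measured in all samples.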

Other observations

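The assays in this part were chosen after their values were seen. miR-223, a myeloid microRNA, had no overlap between the groups after mean Ct normalization. Its change was 2.15 ± 0.93 (SE; unadjusted exact permutation p = 0.0286, limma adjusted p = 0.381), while in the authors' values it was -1.88 (limma adjusted p = 0.476). After mean Ct normalization 3 assays had groups that did not overlap: miR-223 (4 samples against 4), miR-363 (3 against 4) and miR-150 (3 against 3). In the authors' values there were 2, miR-218 (4 against 3) and miR-150 (3 against 3). For miR-150 this depends on the value subtracted in long sample 2. Chance alone gives 2.86% of assays without overlap for 4 samples against 4, 5.71% for 4 against 3 and 10% for 3 against 3, or 1.59 of the 31 tested assays.

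miR-203, known from epithelial cells, was detected in 3 of 4 short samples at a mean Ct of 27.3 ± 0.268 (SD, n = 3) and in 0 of 4 long samples. miR-484 was detected in 3 of 4 long samples at 28.5 ± 1.39 (SD, n = 3) and in 0 of 4 short samples. miR-624 had a Ct in all 4 short and 0 long samples, each above 35. At a Ct of at most 35, 19 assays were detected in the short group alone and 27 in the long group alone, and Fisher's exact test called 0 of 87 after adjustment, with 2 at an unadjusted p under 0.05.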
